A study of Homo sapiens with 22 samples.

How the data were processed

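Jurkat cells, an established line of human T-cell leukaemia cells, were profiled by bulk ATAC-seq, an assay in which a transposase cuts and tags accessible chromatin. Per the labels, 50000 cells went into each reaction, libraries were amplified for 8 PCR cycles and sequenced on an Illumina NextSeq instrument with a target of 2000000 read pairs per library. The 22 libraries form 11 groups of 2: cells stimulated with anti-CD3 and anti-IgG antibodies for 9 durations, and untreated cells labelled 8 h or 24 h. The labels do not say whether replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

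The authors deposited 1 processed table with a deviation z score for each of 746 transcription factor motif matrices in each library. Per the labels, the genome build was GRCh38. The aligner, the peak caller, the tool behind the z scores and its background sites are not given in the sources used here. Motif deviation scores in general compare accessibility at sites that carry a motif with accessibility at matched background sites. Over the 22 libraries the mean score of a matrix ranged from -0.268 to 0.867, so the deposited scores are close to relative to the average of these libraries, and the sign of a single score has no absolute meaning. The depth that each library reached is unknown, and z scores grow with depth. The table holds no counts, no genomic positions and no peaks, so no interval for counting error and no location can be given. A matrix is not a protein: matrices of related factors share sites, and a score does not show which family member is bound.

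Scores were analysed as deposited, with no filter and no transformation, in R 4.3.3 with limma 3.58.1. A group-means model over the 11 groups was fitted to each matrix with lmFit, contrasts were tested with eBayes at default settings (11 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all matrices within a contrast. All tests were 2-sided, and a result was called at an adjusted p of 0.05. Differences are in units of z and are given with the standard error of the fit. That error rests on the spread between the 2 libraries of a group. Where durations or the 2 control groups are pooled, it leaves out the spread between them, and n counts libraries. Each stimulated group was compared with the mean of both control groups, and the 8 h and 24 h stimulated groups with the control of the same label. The other contrasts were the early window (30 min, 1 h, 90 min and 2 h) minus controls, the late window (8 h, 16 h and 24 h) minus controls, early minus late, the 24 h response minus the 8 h response, and the 24 h minus the 8 h controls, with a moderated F test over the 9 durations. Controls existed for 2 of the 9 durations, so differences at other durations include any change with time in culture.

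Fixed lists of factors by family were scored as the mean z over the list's matrices in each library. Of the 45 lists, 42 held at least 2 matrices and were tested with limma across lists; 3 held a single matrix and are reported as that matrix. The result of 1 list is not reported here. In all, 380 matrices stood in a list and 366 in none. Members were also counted in the test over all matrices and adjusted over the list alone. The list test asks whether the members' mean moved. Beside it, camera in limma, with a correlation between members estimated from the data, asks whether members moved beyond the other matrices. Its adjusted p is given where it ends a call.

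The windows, the contrasts, the lists, the rule for named matrices and most alternatives were fixed before the data were examined. For the early window and for the matched 8 h and 24 h comparisons, the rule takes the 10 largest called differences each way among matrices whose stimulated libraries all lie on 1 side of all controls, with 1 matrix per factor. It takes 5 each way for early minus late, and adds 53 fixed factors present in the table out of 54.

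The alternatives tried were the replicate number as a block, each library divided by its SD over matrices, matrices with an SD under 1.5 left out, 1 matrix per factor symbol, eBayes with trend and robust, only the compared groups in the fit, only 1 control group as the reference, a 2-group fit, the median of a list's members, camera, and each library left out in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. The early window without 30 min, and 1 control group as the reference for list scores, were added after seeing the data, as was division by the interquartile range for 2 list differences. Dividing by the SD removes a common scale such as depth, but the SD of a library is itself set largely by the AP-1 matrices. It therefore also removes part of a real AP-1 change. Between libraries that all have low AP-1 scores, as in the controls and at 16 h and 24 h, it can remove most of it. A lost AP-1 call there does not decide. The fit was tested on simulated data in which 200 of the 746 matrices were shifted by 2, 4 or 8 z units. For the early window it called 56.7% of shifts of 2 z units and 95.5% of shifts of 4, with 4 false calls. For the matched 8 h comparison it called 26.9% and 85.1%, with 8 false calls. The simulated noise was independent between matrices, and each shift was equal across durations. Real matrices share sites and real changes differ between durations, so these rates may not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.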

Results

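The data were motif deviation scores from 22 ATAC-seq libraries of Jurkat cells: 18 from cells stimulated through the T-cell receptor for 30 min, 1 h, 90 min, 2 h, 3 h, 4 h, 8 h, 16 h or 24 h, and 4 from untreated cells labelled 8 h or 24 h, each with n = 2. A higher score means that sites with the motif were more accessible, relative to background sites, than in another library of this set. The SD over the 746 matrices ranged from 1.75 in an 8 h stimulated library to 7.02 in a 24 h control. Across matrices, which are not independent replicates, the Pearson r between the 2 libraries of a group was 0.889 to 0.978 in 10 groups and 0.54 in the stimulated 8 h group, whose root mean square difference between replicates of 1.73 lay within the 1.35 to 2.04 of the other groups.

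The untreated cells set the background, and they were not alike at 8 h and 24 h. E-box motifs scored higher in the 24 h controls: the ZEB/SNAI list, zinc-finger repressors that bind a subset of E-boxes, by 6.46 ± 0.56 (SE, n = 2 against 2), with 4 of 4 matrices higher. The E-protein/TAL1 list, the class of basic helix-loop-helix factors that guides T-cell development, was higher by 4.52 ± 0.58, with 5 of 7. The muscle and neural bHLH list, which shares E-box sequences with both, was higher by 3.18 ± 0.45, with 13 of 23 (14 adjusted over the list alone). The MYC/E-box list also scored 1.66 ± 0.48 higher, with 2 of 22 (9 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation). It lost its call without control 8 h replicate 1 (1.46) or control 24 h replicate 1 (1.51). The AP-1 list was lower in the 24 h controls by a difference of -4.30 ± 1.34, with 10 of 34 matrices (18 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). Its sign turned to 0.332 after each library was divided by its SD, which AP-1 matrices largely set, so this division cannot test it. The call was lost without control 24 h replicate 1 (-4.15) or 2 (-4.45) or control 8 h replicate 2 (-3.27). The NFAT list (-2.20), the RUNX list (-2.52) and the SPI list (-2.52) were lower too (adjusted p = 0.376, 0.376 and 0.319 with an estimated correlation). Each of these calls was lost when single libraries were left out. NFAT lost it without control 24 h replicate 2 (-1.35) or control 8 h replicate 1 (-1.87) or 2 (-2.52). RUNX lost it without control 24 h replicate 1 (-2.37) or control 8 h replicate 2 (-1.23), while without control 8 h replicate 1 it was -3.82. SPI lost it without control 24 h replicate 1 (-2.45) or control 8 h replicate 2 (-2.50). In all, 50 of 746 matrices differed (limma), 35 higher and 15 lower at 24 h. That count fell to 32 or 22 without control 8 h replicate 1 or 2 and to 20 without control 24 h replicate 2. With each library divided by its SD, limma called 0 matrices (17 at an unadjusted p) and none of the 42 lists.

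The 30 min libraries ask what stimulation did at the shortest duration. The NFAT list, the factors that calcineurin sends to the nucleus after calcium entry, rose by 13.8 ± 0.62 (n = 2 against 4 controls), with 5 of 5 matrices. The RFX list, winged-helix factors that bind X-box motifs in promoters, rose by 12.2 ± 0.50, with 6 of 6. The AP-1 list, the FOS and JUN dimers induced by MAP kinase signalling, rose by 13.2 ± 1.16, with 34 of 34 (3.91 after each library was divided by its SD). These 3 lists also passed with an estimated correlation. Smaller rises were called for MAF/NFE2/BACH, bZIP factors that share part of the AP-1 motif (6.71 ± 0.72, 9 of 15 matrices, 10 adjusted over the list alone; 1.69 after division by the SD), MEF2, calcium-responsive MADS-box factors (4.64 ± 0.74, 4 of 4), and NFY, which binds CCAAT boxes (4.39, 3 of 3). So were rises for EGR, zinc-finger products of immediate early genes (3.87 ± 0.61, 4 of 4; 2.35 after division by the SD), CTCF, the insulator protein (3.65 ± 0.66, 2 of 2; 5.89 after division by the SD), CREB/ATF (2.78 ± 0.48, 8 of 14, 9 adjusted over the list alone) and SP/KLF (2.30 ± 0.48, 14 of 21, 16 adjusted over the list alone). With an estimated correlation the adjusted p of these lists was 0.186 (MAF/NFE2/BACH), 0.315 (MEF2), 0.450 (NFY), 0.299 (EGR), 0.370 (CTCF), 0.218 (CREB/ATF) and 0.337 (SP/KLF). The NF-kB list rose by 2.23 ± 0.50, with 2 of 5 (4 adjusted over the list alone; adjusted p = 0.450 with an estimated correlation), but not without stimulated 30 min replicate 1 (1.33, adjusted p = 0.0511). The YY1 list (2.02; 1.35 and not called without stimulated 30 min replicate 2) and the FOX list (1.63) were called as well (adjusted p = 0.549 and 0.589 with an estimated correlation). The FOX call was lost without control 8 h replicate 2 (1.27) or stimulated 30 min replicate 1 (1.69) or 2 (1.57).

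Other lists fell at 30 min. The ZEB/SNAI list fell by 6.92 ± 0.48, with 4 of 4 matrices, and the E-protein/TAL1 list by 4.86 ± 0.50, with 6 of 7, and both passed with an estimated correlation. Against the 8 h controls alone these differences were -3.69 and -2.60, still called, and after division by the SD they were -3.48 and -2.83. The muscle and neural bHLH list fell by 2.57 ± 0.39, with 13 of 23 (15 adjusted over the list alone). It was not called against the 8 h controls alone (-0.987) or after division by the SD (-0.846), and was -4.16 against the 24 h controls alone. The SPI list, ETS-class factors of myeloid and B cells, fell by 4.33 ± 0.59 (3 of 3), and the GATA list, which includes the T-cell factor GATA3, fell by 4.13 ± 0.58 (7 of 7). The RUNX list, core T-cell factors, fell by 3.26 ± 0.61 (2 of 3; -1.999 against the 24 h controls alone) and the ETS list fell by 3.13 ± 0.53 (9 of 23, 10 adjusted over the list alone; -1.66 as the median of its members). With an estimated correlation the adjusted p was 0.140 (SPI), 0.123 (GATA), 0.299 (RUNX) and 0.218 (ETS). The TFAP2 list (-2.11, 4 of 10; adjusted p = 0.315 with an estimated correlation) and the TCF/LEF list, nuclear partners of beta-catenin (-2.67 ± 0.75, 3 of 4; adjusted p = 0.370 with an estimated correlation), fell too, the latter not against the 24 h controls alone (-1.77). The single IKZF1 matrix, for the lymphoid factor Ikaros, went from group means of 1.96 and 0.223 in the controls to -7.04. In all, 184 matrices were called, 115 higher and 69 lower, a count that was 122 without stimulated 30 min replicate 1 and 90 with each library divided by its SD.

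**Figure D1:**
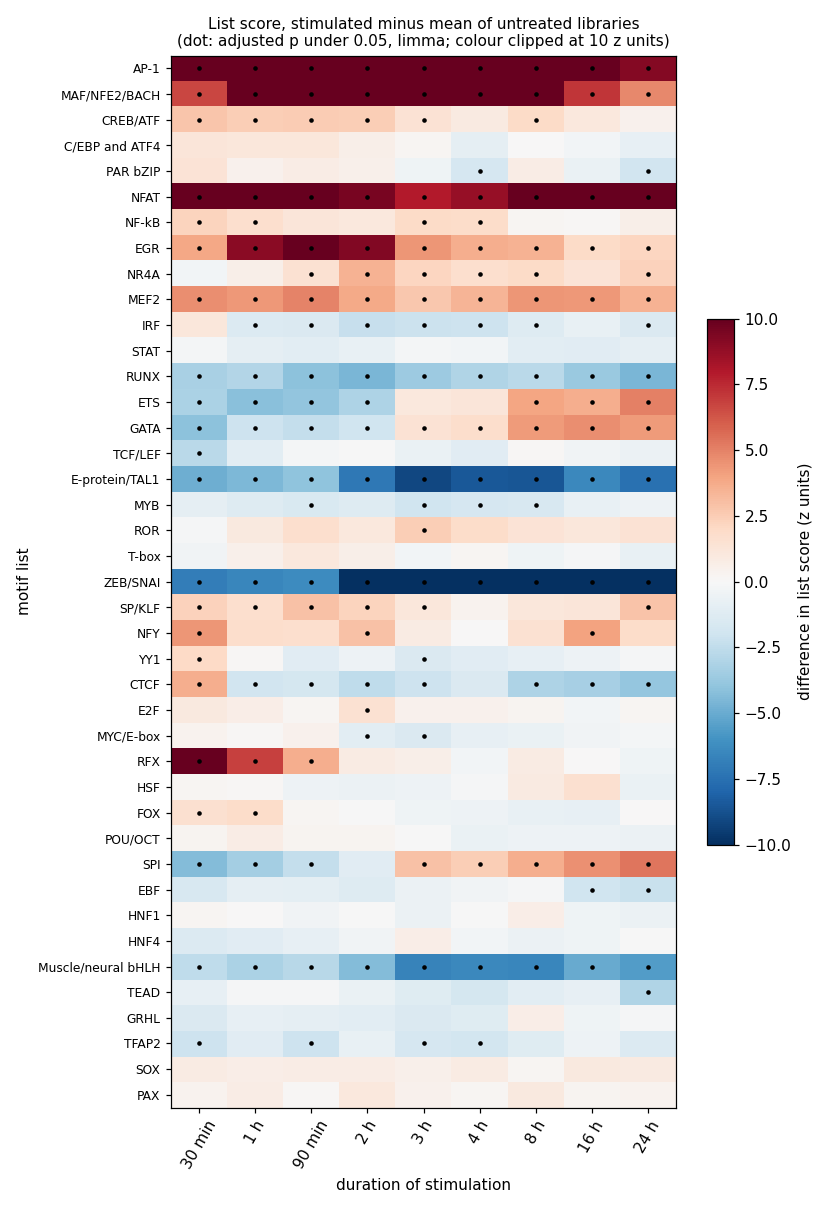
Difference in list score between each duration of stimulation and the mean of the 4 untreated libraries (z units, colour clipped at 10), for the lists with at least 2 matrices, 1 of them not shown; a dot marks an adjusted p under 0.05 (limma). AP-1, NFAT and EGR carry a dot at all 9 durations. With each library divided by its SD the EGR difference at 16 h turns to -0.578. The EGR calls at 4 h (2.25), 8 h (0.689) and 24 h (0.454) are then lost. So are the AP-1 calls at 16 h and 24 h, but AP-1 matrices largely set the SD, so this division cannot test them. The EGR call at 16 h (1.89) is also lost without stimulated 16 h replicate 2 (1.16), control 8 h replicate 1 (1.73) or control 24 h replicate 2 (1.78) and against the 24 h controls alone (1.51), and the call at 24 h (2.15) without stimulated 24 h replicate 1 (1.85) and against the 24 h controls alone (1.77). With an estimated correlation (camera), EGR passes at no duration, NFAT does not pass at 90 min, 2 h, 3 h or 4 h, and AP-1 does not pass at 24 h.

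The early window runs from 30 min to 2 h. AP-1 motifs rose by 30.6 ± 0.82 (n = 8 against 4), with 34 of 34 matrices and an adjusted p of 4.6e-17 (limma). The list means ran from -7.78 at 30 min to 18.9 at 2 h, a spread between durations that this error leaves out. The largest single rises were FOS::JUND (50.3 ± 1.69), FOSL2::JUN (50.1 ± 1.59) and FOSL1::JUN (48.9 ± 1.48); BATF, an AP-1 partner of lymphocytes, rose by 47.5 ± 1.31. The rule that picked the largest rises required all 8 stimulated libraries to lie above all 4 controls, so that separation is no added evidence. The MAF/NFE2/BACH list rose by 16.5 ± 0.51, with 13 of 15 matrices (adjusted p = 0.0524 with an estimated correlation), led by BACH2, a repressor in lymphocytes that recognises an extended AP-1 site (38.9 ± 1.02). The NFAT list rose by 12.9 ± 0.44, with 5 of 5 (adjusted p = 0.0524 with an estimated correlation); NFATC1 rose by 13.4 ± 0.62. The EGR list rose by 8.06 ± 0.43, with 4 of 4 (adjusted p = 0.107 with an estimated correlation), and EGR3 by 9.40 ± 0.62. The RFX list rose by 5.89 ± 0.35, with 6 of 6 (adjusted p = 0.0796 with an estimated correlation), and by 3.77 when the 30 min libraries were left out. MEF2 rose by 4.44 ± 0.52 (4 of 4; adjusted p = 0.420 with an estimated correlation). CREB/ATF rose by 2.57 ± 0.34 (12 of 14; adjusted p = 0.288 with an estimated correlation) with CREB1 at 5.08 ± 0.67. SP/KLF, GC-box factors of promoters, rose by 2.30 ± 0.34 (16 of 21; adjusted p = 0.420 with an estimated correlation).

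NF-kB motifs moved little over the same window. The list rose by 1.55 ± 0.35, with 2 of 5 matrices (3 adjusted over the list alone; adjusted p = 0.738 with an estimated correlation): REL rose by 2.09 and RELA by 2.13, whereas NFKB1 (1.12), NFKB2 (1.23) and RELB (1.18) were not called. REL was not called against the 8 h controls alone (1.52), nor RELA after division by the SD (1.88). The NFY list (2.71, 3 of 3), the NR4A list, orphan nuclear receptors induced by antigen signals (1.33, 1 of 3), and the C/EBP and ATF4 list (1.01, 2 of 8) were called higher (adjusted p = 0.738, 0.897 and 0.897 with an estimated correlation). None of these 3 calls held after division by the SD (2.38, 0.575 and 1.004). NFY was not called against the 24 h controls alone (2.09), NR4A without control 24 h replicate 1 (1.10), and C/EBP and ATF4 against the 8 h controls alone (0.189) or without control 24 h replicate 1 (0.679) or control 8 h replicate 2 (0.824). The single SRF matrix, for the serum response factor, differed by 1.77 (adjusted p = 0.0238), and was not called without control 8 h replicate 1 (1.59), control 24 h replicate 1 (1.65) or stimulated 2 h replicate 2 (1.504), nor after division by the SD (1.43). The STAT, T-box, HSF, ROR, POU/OCT, SOX and PAX lists and the single NRF1 matrix were not called in this window, nor were the E2F, YY1, CTCF, FOX, TCF/LEF, PAR bZIP, MYC/E-box, EBF, HNF1, HNF4, TEAD and GRHL lists.

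Against this, the ZEB/SNAI list fell by 7.56 ± 0.34 in the early window, with 4 of 4 matrices. The E-protein/TAL1 list fell by 5.14 ± 0.35, with 6 of 7, and the muscle and neural bHLH list fell by 3.20 ± 0.28, with 16 of 23 (17 adjusted over the list alone). All 3 passed with an estimated correlation. Against the 8 h controls alone they were smaller but still called (-4.33, -2.88 and -1.61), as they were after division by the SD (-4.30, -3.11 and -1.74). The largest single falls were SNAI1 (-10.0 ± 0.63; -5.00 against the 8 h controls alone, -15.1 against the 24 h controls alone and -5.86 after division by the SD) and TCF4, an E protein (-8.62 ± 0.57; -5.24 against the 8 h controls alone and -5.09 after division by the SD). ETV1, an ETS factor, was next (-8.06 ± 0.79). The ETS list, whose members include the T-cell factor ETS1, fell by 3.58 ± 0.38, with 20 of 23 (adjusted p = 0.107 with an estimated correlation), and GABPA, an ETS factor of promoters, by 7.57 ± 0.70. RUNX fell by 3.71 ± 0.43 (3 of 3; adjusted p = 0.280 with an estimated correlation; -2.45 against the 24 h controls alone), with RUNX1 at -5.09 ± 0.59. SPI fell by 2.80 ± 0.42 (3 of 3; adjusted p = 0.284 with an estimated correlation; -1.54 against the 24 h controls alone) and GATA fell by 2.65 ± 0.41 (6 of 7, 7 adjusted over the list alone; adjusted p = 0.280 with an estimated correlation). The IRF (-1.01), MYB (-1.26) and TFAP2 (-1.51) lists were called lower, with 2 of 10, 0 of 3 and 5 of 10 matrices in limma, but adjusted p = 0.519, 0.547 and 0.462 with an estimated correlation. None of the 3 calls held after division by the SD (-0.497, -0.860 and -1.21). IRF was -1.73 without the 30 min libraries and -0.306, not called, against the 24 h controls alone. It was not called without control 24 h replicate 1 (-0.663) or control 8 h replicate 1 (-0.976). MYB was not called without control 24 h replicate 2 (-0.968) or against the 8 h controls alone (-0.774). In all, 262 matrices were called, 162 higher and 100 lower, and 155 with each library divided by its SD.

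**Figure D2:**
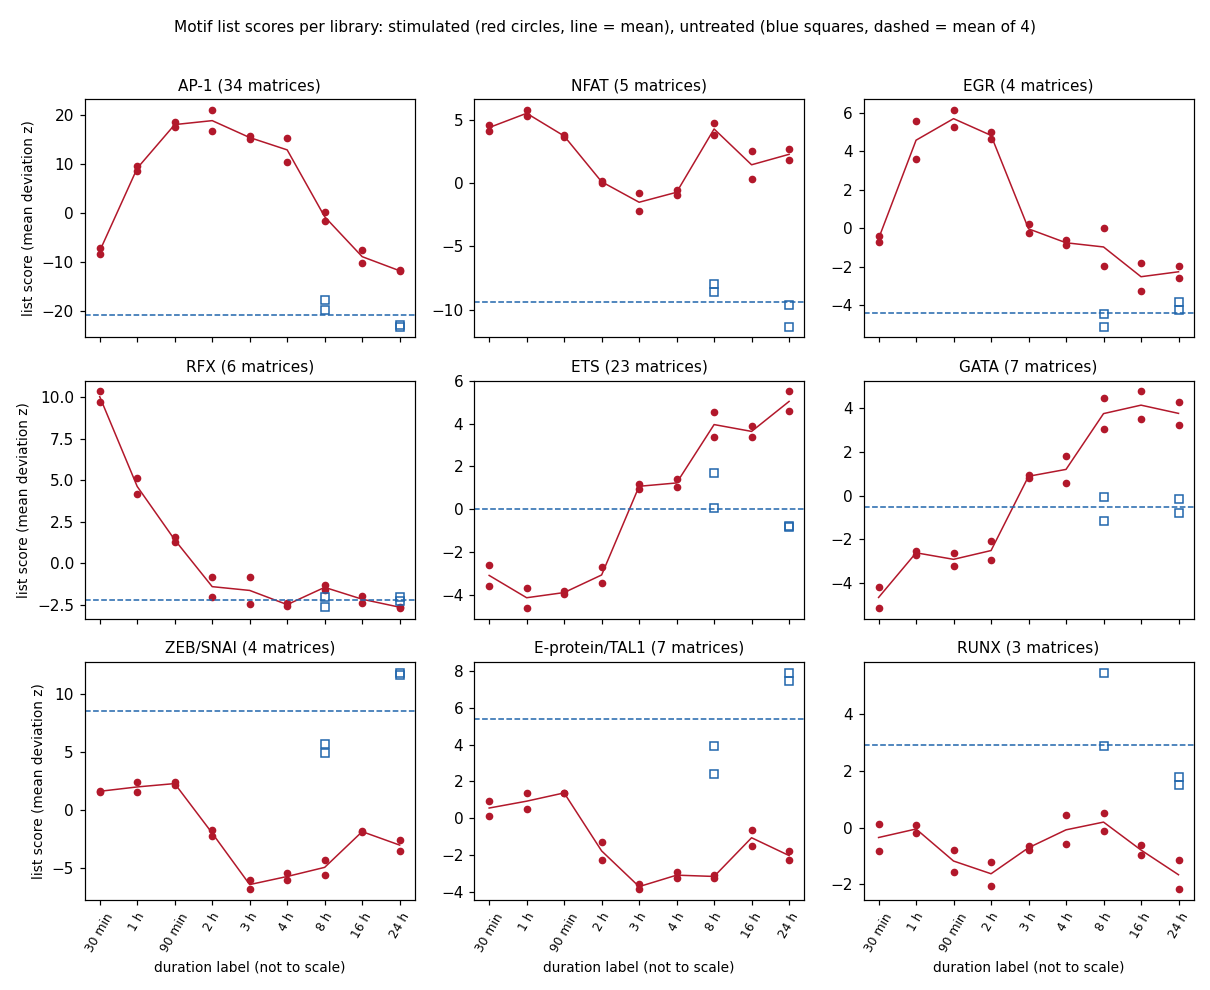
List score (mean deviation z) per library against the duration label, for 9 lists; red circles are stimulated libraries with a line through the group means, blue squares are untreated libraries and the dashed line is their mean (n = 2 per group). AP-1 means run from -7.78 at 30 min to 18.9 at 2 h and -11.8 at 24 h against -18.8 and -23.1 in the controls. The matched difference at 24 h is not called after division by the SD (0.457), but AP-1 matrices largely set that SD.

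Over the 9 durations, 209 of 746 matrices and 23 of 42 lists changed with time among stimulated libraries (moderated F test). The AP-1 list went from a mean of -7.78 ± 0.87 (SD, n = 2) at 30 min to 18.9 ± 3.03 at 2 h and back to -11.8 ± 0.17 at 24 h, against -21.0 ± 2.63 in the 4 controls. In a contrast chosen after the values were seen, 2 h exceeded 30 min by 26.7 and 24 h by 30.8. EGR means peaked at 5.70 at 90 min and were -0.0343 by 3 h, against -4.80 and -4.04 in the controls. The 3 h difference from the controls was 4.38 ± 0.61 and still called (3.03 after division by the SD), but did not pass with an estimated correlation. RFX fell from 10.0 at 30 min to 4.62 at 1 h, 1.42 at 90 min and -1.40 at 2 h, against -2.30 and -2.14 in the controls. The difference between 30 min and 2 h was 11.4 ± 0.58 (adjusted p = 1.9e-12, contrast chosen after the values were seen). NFAT motifs had a dip. The list averaged 5.54 at 1 h, 0.115 at 2 h, -1.51 at 3 h, -0.716 at 4 h and 4.29 at 8 h, and remained above the controls (-8.31 and -10.5) throughout. The ETS list crossed the controls between 2 h (-3.10 ± 0.53 against controls) and 3 h (1.04, not called), and was 3.92 ± 0.53 at 8 h. The GATA list crossed them between 2 h (-1.99) and 3 h (1.41), and was 4.28 at 8 h. The 3 h GATA call was lost after division by the SD (1.16) and without stimulated 3 h replicate 1 (1.35) or 2 (1.48). Neither list passed with an estimated correlation at 2 h, 3 h or 8 h. The 2 h GATA call was lost without stimulated 2 h replicate 1 (-1.55) and after division by the SD (-1.54). The IKZF1 matrix followed the same course, from -7.04 at 30 min to 2.30 at 3 h and 7.23 at 24 h. CTCF rose at 30 min alone: its list mean was 5.16 there, against 0.518 and 2.50 in the controls and -1.04 at 2 h, and 30 min exceeded 2 h by 6.20 ± 0.76 (contrast chosen after the values were seen). The IRF list, antiviral and lymphoid regulators, was 3.46 lower at 2 h than at 30 min, a difference of -3.46, in a contrast of the same kind. Against the pooled controls ROR was called at 3 h only (2.49), and not without stimulated 3 h replicate 2 (1.63), against the 24 h controls alone (1.66) or after division by the SD (2.10). It did not pass with an estimated correlation either.

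The numbers of called matrices against the pooled controls were 203 at 1 h, 206 at 90 min, 216 at 2 h, 151 at 3 h, 139 at 4 h, 155 at 8 h, 136 at 16 h and 195 at 24 h. They were 129 at 1 h without stimulated 1 h replicate 1 and 132 at 2 h without stimulated 2 h replicate 2. At 90 min 128 were higher and 78 lower, which became 62 and 17 after division by the SD and 123 and 46 against the 8 h controls alone. At 16 h the split of 80 higher and 56 lower became 40 and 47 after division by the SD. Among the 209 matrices that changed with time, 39 were highest at 30 min, 43 at 1 h, 38 at 90 min, 36 at 2 h and 31 at 24 h. The lowest value fell at 24 h for 64 of them.

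The matched 8 h comparison asks what stimulation changed against cells with the same label. AP-1 motifs were still high: the list rose by 18.1 ± 1.34 (n = 2 against 2), with 22 of 34 matrices (24 adjusted over the list alone), and 27.4 as the median of its members. FOS::JUND rose by 29.9 ± 2.77 and BATF by 27.8. NFAT rose by 12.6 ± 0.72, with 5 of 5, and NFATC3 by 13.6 ± 0.93. The MAF/NFE2/BACH list rose by 9.53 ± 0.83, with 8 of 15 (9 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation; 5.81 after division by the SD). The GATA list rose by 4.35 ± 0.67, with 6 of 7 (7 adjusted over the list alone), and the ETS list by 3.08 ± 0.62, with 12 of 23 (18 adjusted over the list alone), with adjusted p = 0.318 and 0.393 with an estimated correlation. These differences were 9.44 and 8.77 after division by the SD. MEF2 rose by 4.43 ± 0.85, with 4 of 4 (adjusted p = 0.453 with an estimated correlation). EGR rose by 3.82 ± 0.71, with 4 of 4 (adjusted p = 0.427 with an estimated correlation), but was not called after division by the SD (1.30). SPI (2.39, 2 of 3; adjusted p = 0.688 with an estimated correlation) was not called without stimulated 8 h replicate 2 (1.58) and was 6.82 after division by the SD. CREB/ATF (2.02, 4 of 14, 5 adjusted over the list alone; adjusted p = 0.552 with an estimated correlation) was not called without control 8 h replicate 2 (1.47).

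E-box lists fell at 8 h, though not MYC/E-box: ZEB/SNAI by 10.2 ± 0.56, with 4 of 4 matrices, and the E-protein/TAL1 list fell by 6.30 ± 0.58. The muscle and neural bHLH list fell by 4.93 ± 0.45, with 16 of 23. All 3 passed with an estimated correlation and grew to -16.0, -10.0 and -8.17 after division by the SD. The stimulated 8 h libraries had the smallest SDs (1.80 and 1.75), so this division enlarges their scores most. SNAI1 fell by 12.9 ± 1.02 and TCF4 fell by 11.98 ± 0.92 (-20.9 and -19.0 after division by the SD). In the E-protein/TAL1 list 5 of 7 matrices fell and 1 rose, GATA1::TAL1, whose motif includes a GATA site (3.53, adjusted p = 0.0128; named after its value was seen). RUNX fell by 3.98 ± 0.70, with 2 of 3 (3 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation). Other list calls at 8 h were weak. IRF (-2.01, 2 of 10, 3 adjusted over the list alone), STAT (-1.57, 1 of 9, 2 adjusted over the list alone) and CTCF (-2.10, 1 of 2) fell, with adjusted p = 0.393, 0.453 and 0.778 with an estimated correlation. Without stimulated 8 h replicate 1 they were not called (-1.31, -1.20 and -1.22), nor was STAT without control 8 h replicate 2 (-1.28) or CTCF without control 8 h replicate 1 (-1.93) or 2 (-2.27). IRF also lost its call after division by the SD (-1.86), whereas CTCF was -4.17. NR4A (1.84), ROR (2.22) and SP/KLF (1.57) were called higher with 0 of 3, 0 of 4 and 1 of 21 matrices in limma, with adjusted p = 0.783, 0.783 and 0.778 with an estimated correlation. NR4A lost its call without each of its 4 libraries: 1.90 and 1.78 without control 8 h replicates 1 and 2, and 1.94 and 1.74 without stimulated 8 h replicates 1 and 2. ROR was 2.06 and 2.39, not called, without the controls, 3.53 and called without stimulated 8 h replicate 1 and 0.909, not called, without replicate 2. It also lost its call at an unchanged 2.22 without any 1 library of 30 min, 1 h or 90 min. SP/KLF was 2.39 and called without control 8 h replicate 1, but 0.751 without replicate 2 and 1.20 without stimulated 8 h replicate 1. After division by the SD, ROR (2.18) and SP/KLF (0.722) were not called. In all, 127 matrices were called, 75 higher and 52 lower.

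The matched 24 h comparison asks the same of the longest duration. NFAT remained high, by 12.8 ± 0.72 (n = 2 against 2), with 5 of 5 matrices and NFATC3 at 15.6 ± 0.93. The AP-1 list rose by 11.3 ± 1.34, with 21 of 34 (22 adjusted over the list alone; adjusted p = 0.140 with an estimated correlation), led by FOSL2::JUN (20.9 ± 2.59) and BATF (20.4 ± 2.14). After division by the SD the AP-1 list was not called (0.457, adjusted p = 0.914 in limma), nor were FOSL2::JUN (2.77) and BATF (2.88). JUNB, at 15.1 before, turned to -0.633. The SD followed the AP-1 scores in these libraries. It was 3.65 and 3.74 in the stimulated and 6.98 and 7.02 in the control libraries, with AP-1 list means of -11.8 and -23.1. This division therefore takes out most of an AP-1 change at 24 h, so the lost calls decide nothing about it. The MAF/NFE2/BACH list rose by 5.52 ± 0.83, with 8 of 15 (adjusted p = 0.472 with an estimated correlation), and turned to -0.0906 after division by the SD. The SPI list rose by 6.63 ± 0.68, with 2 of 3 (3 adjusted over the list alone), and the ETS list by 5.84 ± 0.62, with 21 of 23 (22 adjusted over the list alone). The GATA list rose by 4.22 ± 0.67, with 6 of 7 (7 adjusted over the list alone). These 3 lists had adjusted p = 0.159, 0.0904 and 0.328 with an estimated correlation. SPI1, the myeloid factor PU.1, whose motif overlaps those of other ETS factors, rose by 7.75 ± 0.88, ETS1 by 5.45 ± 0.93 and IKZF1 by 7.01. SP/KLF rose by 2.44 ± 0.55, with 8 of 21 (17 adjusted over the list alone; adjusted p = 0.475 with an estimated correlation). MEF2 (3.46, 3 of 4, 4 adjusted over the list alone) and NR4A (2.37, 1 of 3) were called higher, both with adjusted p = 0.712 with an estimated correlation. MEF2 was not called without control 24 h replicate 2 (2.52) or stimulated 24 h replicate 2 (2.51) or after division by the SD (2.19), nor NR4A without control 24 h replicate 1 (1.92) or after division by the SD (2.001).

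At 24 h ZEB/SNAI fell by 14.8 ± 0.56, with 4 of 4 matrices. E-protein/TAL1 fell by 9.69 ± 0.58, with 5 of 7, and the muscle and neural bHLH list fell by 7.19 ± 0.45, with 16 of 23 (17 adjusted over the list alone). All 3 passed with an estimated correlation. SNAI1 fell by 20.6 ± 1.02, TCF4 by 16.4 and TCF3, the E protein E2A, by 16.2. The CTCF list fell by 4.89 ± 0.76, with 2 of 2 (adjusted p = 0.385 with an estimated correlation), and the CTCF matrix by 6.97 ± 1.14. RUNX fell by 3.31 ± 0.70, with 2 of 3 (adjusted p = 0.507 with an estimated correlation). TEAD (-2.62, 2 of 4) and PAR bZIP (-2.12, 0 of 4 in limma, 2 adjusted over the list alone) were called lower, both with adjusted p = 0.729 with an estimated correlation. TEAD was not called without control 24 h replicate 1 (-2.39) or stimulated 24 h replicate 1 (-2.21), nor PAR bZIP without control 24 h replicate 1 (-2.07) or 2 (-2.17) or stimulated 24 h replicate 1 (-1.73). After division by the SD neither TEAD (-2.75) nor PAR bZIP (-2.30) was called. EGR, at 1.77, was not called. In all, 159 matrices were called, 89 higher and 70 lower, and 75 after division by the SD.

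The responses at 8 h and 24 h share no library and were alike across matrices, which are not independent replicates. Pearson r was 0.900 and Spearman rho 0.680, and r was 0.868 over the 697 matrices outside the AP-1 and MAF/NFE2/BACH lists. After division by the SD r was 0.709. Of the called matrices, 59 were higher at both durations where independent calls would give 8.95, and 47 were lower at both where independent calls would give 4.88. The difference between the responses passed the test for 4 matrices and 8 lists. The count of 4 was 17 with the replicate block, 41 with only the compared groups and 51 after division by the SD, and 0 to 31 with 1 library left out. The 0 (limma) came without control 8 h replicate 1, control 24 h replicate 1 or stimulated 8 h replicate 1 (83, 90 and 78 at an unadjusted p), and the 31 without either stimulated 2 h library. The AP-1 list rose less at 24 h, by a difference of -6.76 ± 1.90 (adjusted p = 0.0191), and the ZEB/SNAI list fell further, by a difference of -4.54 ± 0.79 (adjusted p = 7.3e-04) that turned to 5.34 after division by the SD. The ZEB/SNAI group means were -4.96 and -3.04 in stimulated cells and 5.29 and 11.7 in the controls at 8 h and 24 h. After division by the SD the gap between the controls was 3.08 and not called. The AP-1 difference was not called without control 8 h replicate 1 (-5.73), control 24 h replicate 2 (-6.62), stimulated 8 h replicate 1 (-5.87) or stimulated 24 h replicate 2 (-6.65), and camera with an estimated correlation called 0 lists (6 at an unadjusted p; adjusted p = 0.0862 for AP-1 and 0.0520 for ZEB/SNAI).

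**Figure D3:**
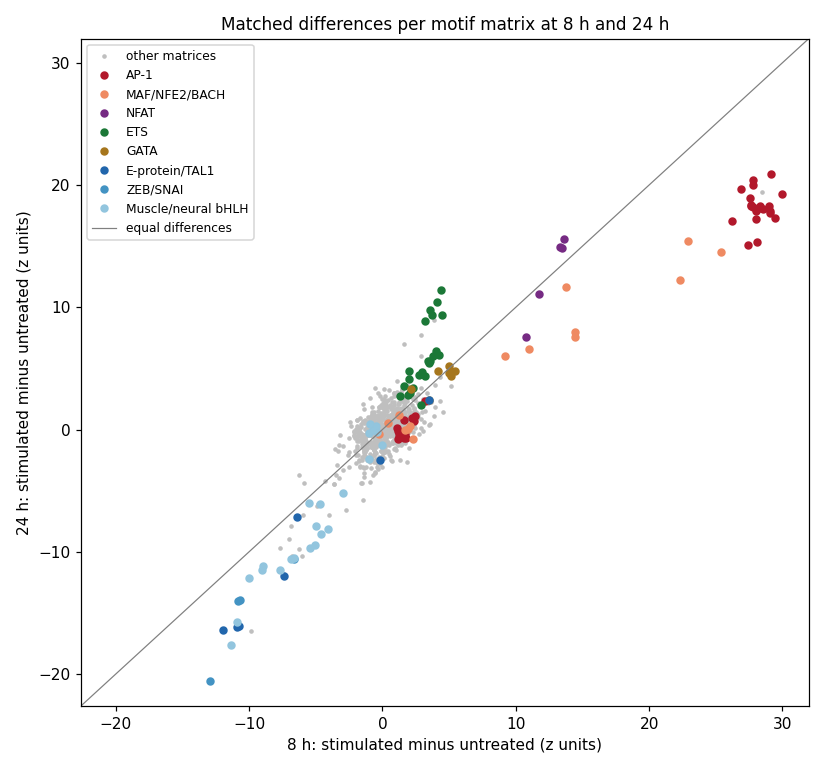
Matched difference, stimulated minus untreated, for each of 746 matrices at 8 h (x axis) and 24 h (y axis), in z units; colours mark 8 lists and the line marks equal differences (r = 0.900 across matrices). The ETS list rose more at 24 h (by 2.76) and the ZEB/SNAI list fell further (a difference of -4.54), but after division by the SD both differences turned sign (-2.48 and 5.34).

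The early and late windows differ (n = 8 against 6). The controls cancel in this contrast, so it includes any change with time in culture. ETS motifs were lower early, by a list difference of -7.76 ± 0.33, with 23 of 23 matrices, GATA by -7.06 ± 0.36, with 7 of 7, and SPI by -7.34 ± 0.37, with 3 of 3. Among the named matrices lower early, GABPA (-15.2 ± 0.62), ETV1 (-15.1) and ELF3 (-14.3) differed most. The AP-1 list was higher early by 16.8 ± 0.73, with 33 of 34 (34 adjusted over the list alone). These 4 lists also passed with an estimated correlation. MAF/NFE2/BACH (9.11 ± 0.45, 12 of 15), RFX (5.74 ± 0.31, 6 of 6; 3.62 without the 30 min libraries), EGR (5.57 ± 0.38, 4 of 4) and ZEB/SNAI (4.25 ± 0.30, 4 of 4; 7.40 after division by the SD) were higher early. So were CTCF (2.78 ± 0.41, 2 of 2; 1.35 without the 30 min libraries and 4.37 after division by the SD), the muscle and neural bHLH list (2.52 ± 0.24, 15 of 23; 4.21 after division by the SD) and E-protein/TAL1 (2.35 ± 0.31, 5 of 7 higher and 1 lower; 4.30 after division by the SD and 4.01 as the median of its members). With an estimated correlation the adjusted p was 0.130 (MAF/NFE2/BACH), 0.0938 (RFX), 0.192 (EGR), 0.114 (ZEB/SNAI), 0.869 (CTCF), 0.104 (muscle and neural bHLH) and 0.774 (E-protein/TAL1). The NF-kB list was higher early by 1.26 ± 0.31, with 3 of 5 (adjusted p = 0.922 with an estimated correlation; 1.98 after division by the SD). The FOX list, forkhead factors, was higher early by 1.41 ± 0.33, with 17 of 30 (23 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation; 2.29 after division by the SD). The NFAT list was not called (0.768, 2 of 5 matrices higher), with NFATC1 at 0.0272 (adjusted p = 0.979). NFATC2 was higher early by 1.40 (adjusted p = 0.0221), but not after division by the SD (0.257), without the 30 min libraries (1.29), or without stimulated 16 h replicate 1 (1.22), 1 h replicate 2 (1.204) or 90 min replicate 1 (1.202). In all, 250 matrices differed, 190 higher and 60 lower early.

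Against the controls, the late window (n = 6 against 4) kept the NFAT rise (12.1 ± 0.46, 5 of 5 matrices) and part of the AP-1 rise (13.8 ± 0.87, 23 of 34, 25 adjusted over the list alone; 4.74 after division by the SD). The ETS list rose by 4.17 ± 0.40, with 22 of 23 (23 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation; 6.78 after division by the SD). The GATA list rose by 4.42 ± 0.43, with 7 of 7 (adjusted p = 0.183 with an estimated correlation; 6.83 after division by the SD). MEF2 rose by 4.07 ± 0.55, with 4 of 4 (adjusted p = 0.446 with an estimated correlation). ZEB/SNAI fell by 11.8 ± 0.36, with 4 of 4, E-protein/TAL1 fell by 7.49 ± 0.37 and the muscle and neural bHLH list fell by 5.72 ± 0.29, with 17 of 23. CTCF fell by 3.43 ± 0.49, with 1 of 2 (2 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). RUNX fell by 3.66 ± 0.45 (3 of 3; adjusted p = 0.314 with an estimated correlation; -2.40 against the 24 h controls alone). The EBF list, B-cell factors, was lower at -1.46 (2 of 3; adjusted p = 0.743 with an estimated correlation). It was not called without control 8 h replicate 1 (-1.39) or 2 (-1.52), control 24 h replicate 2 (-1.002) or any of stimulated 8 h replicate 2 (-1.38), 16 h replicate 2 (-1.31) and 24 h replicate 2 (-0.995), nor after division by the SD (-1.07). In all, 211 matrices were called, 130 higher and 81 lower. Across matrices, which are not independent replicates, the early and late responses correlated with r = 0.879 and rho = 0.581 (r = 0.613 outside the AP-1 and MAF/NFE2/BACH lists, and 0.436 after division by the SD), with a covariance of 37.2. They share their controls, which alone gave a simulated r of 0.632 and covariance of 0.289. With the controls split, r was 0.825 (covariance 38.1) for early against the 8 h and late against the 24 h controls, and 0.889 (34.1) for the reverse. Of the called matrices, 83 were higher in both windows and 50 lower in both, and 31 were called in opposite directions. Independent calls would give 28.2 and 10.9, which leaves out the shared controls, and 100 simulations of unchanged groups against shared controls gave at most 0 and 1 (limma), which leaves out the effects.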

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

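Of the tests in this part, those that use interquartile ranges or ratios between libraries, the promoter lists at 30 min, the splits that keep groups whole and the NFAT contrast of 2 h to 4 h against 1 h and 8 h, with all tests of it, were chosen only after the results were seen, and the 3 patterns below were picked from their values. The following results stood out because the response at 24 h differed from the response at 8 h in a test of that difference (limma, n = 2 per group). Among single matrices these were SNAI1 (-7.70 ± 1.45, adjusted p = 0.0165), Rbpjl (-6.64 ± 1.48, adjusted p = 0.0449), JUNB (-12.3 ± 2.69, adjusted p = 0.0449) and GABPA (7.02 ± 1.63, adjusted p = 0.0492). Of these, only JUNB was called after division by the SD (-19.9); SNAI1 (6.01), Rbpjl (4.23) and GABPA (-0.631) turned sign and were not. Without control 8 h replicate 1, control 24 h replicate 1 or stimulated 8 h replicate 1 none of the 4 was called (limma called 0 matrices, with 83, 90 and 78 at an unadjusted p). Without control 24 h replicate 2 only SNAI1 was called (-8.32), without stimulated 24 h replicate 1 only GABPA (9.52), and without stimulated 24 h replicate 2 only SNAI1 (-8.96) and Rbpjl (-7.94). GABPA also lost its call without control 8 h replicate 2 (6.19) or stimulated 8 h replicate 2 (7.41). Calls were lost at unchanged differences without a library of 30 min, 1 h, 90 min or 16 h, which do not enter this contrast. Without a library of 2 h, 3 h or 4 h more matrices were called. Among lists these were AP-1 (-6.76), MAF/NFE2/BACH (-4.003), PAR bZIP (-3.00), ETS (2.76), E-protein/TAL1 (-3.39), ZEB/SNAI (-4.54), SPI (4.24) and muscle and neural bHLH (-2.26). After division by the SD 5 of these 8 turned sign: ETS (-2.48), E-protein/TAL1 (3.01), ZEB/SNAI (5.34), SPI (-0.198) and muscle and neural bHLH (2.83). The SD was 1.80 and 1.75 in the stimulated 8 h libraries and 3.65 and 3.74 in the stimulated 24 h libraries. The division therefore enlarges 8 h scores relative to 24 h scores. camera with an estimated correlation called 0 lists (6 at an unadjusted p), and limma called 3 lists without control 8 h replicate 1 or stimulated 24 h replicate 2 and 5 without control 24 h replicate 1 or 2. Between the early and the late window 250 matrices differed. In 2-group fits over splits of single libraries, 1 of 100 splits, the real one, gave as many matrices for early minus controls (211, highest other 26). The same held for late minus controls (167, highest other 36) and early minus late (199, highest other 99). These splits part the 2 libraries of a group, which widens the spread within each side and lowers the counts, so they cannot exclude chance. With groups kept whole, 1 of 35 splits for early minus late, the real one, gave as many (199, highest other 131). That is the smallest share that 35 splits can give. The groups are durations ordered in time and not interchangeable, so this share cannot exclude chance either. The 15 whole-group splits for early minus controls (211; highest other 55) and the 10 for late minus controls (167; highest other 36) are too few for a share under 0.05.

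The E-box lists were higher in the 24 h than in the 8 h controls, so the size of the ZEB/SNAI and E-protein/TAL1 differences above depends on the control used. A single divergent control library is argued against by the largest adjusted p of the ZEB/SNAI list without 1 of the 4 control libraries, 3.4e-06. A common depth factor on all z values is argued against as the whole cause for the ZEB/SNAI, E-protein/TAL1 and muscle and neural bHLH lists. Each of these was at least 1.90 times as high in a 24 h as in an 8 h control library. The largest such ratio was 1.332 for the SD and 1.31 for the AP-1 list score. It was 0.979 for the interquartile range over 663 matrices outside these lists and the AP-1 and MAF/NFE2/BACH lists. The range of matrices that do not respond need not follow depth, so this last ratio decides nothing. The MYC/E-box list was not part of this test. Division by the SD ended the ZEB/SNAI call, since the difference fell and its error rose (6.46 ± 0.56 before; 3.08 ± 0.98 after, adjusted p = 0.172). Division by the interquartile range, which need not follow depth, left 6.57 ± 0.56. Time in culture may explain the gap and stays open, as untested.

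The NFAT list was lower at 2 h to 4 h than at 1 h and 8 h, by a difference of -5.62. A uniform offset was not seen: the median change was -0.210 (interquartile range -0.705 to 0.336) over 692 matrices outside the AP-1, MAF/NFE2/BACH and NFAT lists. This check was weak. The median over all matrices lay between -0.462 and 0.571 in every library, so scores set against background sites leave little room for such an offset. A single divergent library is argued against by the largest adjusted p without 1 of the 10 libraries, 2.0e-07. Smaller z values overall stay open. The gap stayed with each library divided by its SD (9.82 ± 0.63). AP-1 matrices set much of the SD, which was 3.49 to 6.23 at 2 h to 4 h and 1.75 to 3.17 at 1 h and 8 h. That division therefore widened the gap. With division by the interquartile range over the same matrices the gap was 5.55 ± 0.46 (larger adjusted p of the 2 fits in limma, 5.8e-08). The NFAT difference from the controls at 2 h to 4 h was 0.608 of that at 1 h and 8 h. No ratio of these ranges between 2 libraries was under 0.759 (1.39 to 1.75 against 1.63 to 1.83). Most of these matrices moved little, and the range of unmoved matrices need not follow depth, so these ranges cannot decide. The duration of stimulation may explain the dip and stays open, as untested.

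The RFX list was highest at 30 min. A single divergent library is argued against by the lower of the 30 min scores, 9.70, against a highest of 5.10 in the other 20 libraries. More promoter-type sites in the 30 min libraries stay open, since promoter lists went both ways: NFY rose by 4.39 and SP/KLF by 2.30, the ETS list differed by -3.13, and NRF1 was not called (1.10, adjusted p = 0.536). The duration of stimulation may explain the peak and stays open too, as untested.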

How the results depend on the processing

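The early window without 30 min and single control groups as the reference for list scores were chosen after seeing the data. Of 156 called matrix results, 122 kept direction and call with each library divided by its SD, and all 156 with the replicate number as a block. Of 285 called list results, 194 kept both under division by the SD and 281 with the block, where 4 lost their call. Whether the replicate numbers pair the libraries is unclear. Differences between replicates correlated from -0.409 to 0.439 over 55 pairs of groups, with 13 pairs over 0.1. Division by the SD moved these counts by over 1.5 times: control 24 h minus control 8 h 0 (limma; 17 at an unadjusted p), 30 min 90, 90 min 79, 2 h 94, 3 h 85, 4 h 75, 16 h 87, 24 h 89, matched 24 h 75 (10 lists), early window 155 and 24 h minus 8 h response 51. By less, it raised 8 h from 155 to 197, matched 8 h from 127 to 166 and early minus late from 250 to 279, and lowered 1 h from 203 to 144 and the late window from 211 to 155; r was 0.709 for 8 h and 24 h and 0.436 for early and late. It turned the sign of EGR3 (matched 8 h, -0.101), JUNB (matched 24 h, -0.633), the AP-1 list (controls, 0.332), the EGR list (16 h, -0.578), the MAF/NFE2/BACH list (matched 24 h, -0.0906) and, for the 24 h minus 8 h response, the ETS (-2.48), E-protein/TAL1 (3.01), ZEB/SNAI (5.34), SPI (-0.198) and muscle and neural bHLH (2.83) lists. Leaving out matrices with an SD under 1.5 gave 163 for early minus late, 31 for the 24 h minus 8 h response and r = 0.929 for 8 h and 24 h, with fewer matrices tested. The 24 h minus 8 h response count was 17 with the replicate block, 14 with trend and robust and 41 with only the compared groups. camera called 4 lists for the early window, 5 at matched 8 h, 4 at matched 24 h, 5 for the late window, 4 for early minus late and 0 for the 24 h minus 8 h response (6 at an unadjusted p). With 1 library left out, counts ranged from 20 to 54 for the controls, 122 to 191 at 30 min, 129 to 210 at 1 h, 132 to 223 at 2 h, and 0 to 31 (lists 3 to 8) for the 24 h minus 8 h response, and r for 8 h and 24 h from 0.884 to 0.900. The 0 (limma) came without control 8 h replicate 1, control 24 h replicate 1 or stimulated 8 h replicate 1 (83, 90 and 78 at an unadjusted p). The cause was not tested. The target was 2000000 read pairs per library; the depth reached is unknown, so how it limits small z differences cannot be given.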

Other observations

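All matrices in this part stand in no list and were chosen after their values were seen. The largest change was Smad2::Smad3, a matrix for partners in TGF-beta signalling, which rose by 48.7 ± 1.44 in the early window (34.9 after division by the SD) and by 22.6 ± 1.52 in the late window (8.35 after division by the SD), sizes close to those of AP-1 matrices. Sites that it shares with AP-1 matrices could not be counted, so its rise does not show a change in TGF-beta signalling. Wt1, a zinc finger whose GC-rich motif resembles that of EGR, rose by 6.36 ± 0.59 in the early window (n = 8 against 4; 4.83 after division by the SD) and was 5.12 higher early than late. ZBTB7A, a zinc-finger repressor of blood lineages, fell by 2.44 ± 0.63 early and rose by 4.16 ± 0.66 late (n = 6 against 4; 6.46 after division by the SD), and Mecom, a factor of blood stem cells, was lower early than late by a difference of -4.51 ± 0.54, the course of the ETS and GATA lists. The sterol-response matrices SREBF2 (3.09 ± 0.61) and SREBF1 (2.81 ± 0.54) rose in the early window (2.23 and 2.12 after division by the SD). In the late window SREBF2 rose by 2.82 ± 0.65 (2.52 after division by the SD) and SREBF1 by 1.74 ± 0.57 (0.941, not called, after division by the SD).

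ZBTB18, a zinc-finger repressor with an E-box motif, fell by 8.35 ± 0.58 in the late window and was 6.31 ± 0.90 higher in the 24 h than in the 8 h controls (3.57, not called, after division by the SD). The TALE homeodomain matrices TGIF1 (-4.52 ± 0.63) and PKNOX2 (-4.93 ± 0.75) fell in the late window (-6.01 and -5.89 after division by the SD), whereas PKNOX1 rose by 2.94 ± 0.71 (2.58, not called, after division by the SD).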
